A study of Mus musculus with 6 samples.

How the data were processed

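Gene expression was measured in whole pancreas of NMRI mice at postnatal day 15 with Affymetrix 3' expression arrays for mouse, 1 array per sample. Per the labels' protocols, biotinylated cRNA was made from 100 ng of total RNA. The values deposited by the authors were log2 probe set summaries. RMA, which corrects background, quantile-normalizes the arrays and summarizes the probes of a set, and Partek 6.5 were the tools named in the submitters' processing notes, with no settings. The values of each array had nearly equal medians (4.38 to 4.42) and quartiles, and ran up to 14.9. Quantile normalization forces the arrays to share a distribution, so a change of total RNA per cell cannot be seen, and RMA compresses differences of dim probe sets.

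The table held 45101 probe sets, of which 64 were Affymetrix controls. The platform annotation gave 34958 probe sets 1 gene symbol, 932 several and 9211 none. Of the named probe sets, 34754 matched a gene identifier in the RefSeq table of the mouse GRCm38.p6 assembly, which gave 0 of them a newer symbol. No gene was named from a probe set with several symbols. The 34958 probe sets measured 18194 genes, 9012 of them with more than 1 probe set, and the probe set with the highest mean over the 6 arrays stood for the gene. The assembly behind the array's design was not given in the sources used here, so no coordinates are printed, and RefSeq was used only for names and for which genes neighbour each other.

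The samples formed 2 groups of 3 by genotype: Prox1-OE (Jojo-Prox1 with Ngn3-cre) and control (Ngn3-cre). Nothing in the labels said whether the samples of a group came from separate animals or litters, so p-values measure only the spread between these samples. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no covariate, no filter on dim genes and Benjamini-Hochberg adjustment over the 18194 genes at 0.05. Unless another test is named, p-values of genes are from limma and two-sided. Probe sets of Prox1 were also tested singly, in a fit of all probe sets.

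Before the data were examined, 31 lists of marker and pathway genes with 589 entries were fixed, of which 531 were measured. Each list was set against all other genes with limma's camera, two-sided, with a preset correlation between genes of 0.01 and adjustment over the 31 lists. Camera with an estimated correlation and fry, a rotation test that does not compare a list with other genes, were run as other tests, chosen before the data were examined. With an estimated correlation, camera also rests on the 4 residual degrees of freedom, in place of a number set by the count of genes. Members past the threshold were counted over all genes and adjusted over the list alone. RNA quality was the log2 difference between the 3' and 5' control probe sets of Gapdh and beta-actin, tested by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1. The number of arrays limits the precision of every value.

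The genes named were fixed by rule before the data were examined: Prox1 and a panel of islet genes, up to 10 genes in each direction past the threshold with groups that did not overlap, and of each list up to 4 members with the smallest p. Of the 14 genes of the panel with Prox1, 11 were measured by a named probe set; the others were not analysed here. G6pc2, Iapp, the chaperone genes Hsp90aa1, Hspb1, Hspa4l and Hspa8, and Glycam1, Ptprc and Marco were chosen after their values were seen. So were a list of lymph node vessel and follicle genes and a list of heat shock genes.

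Other settings, also chosen before the data were examined, were the mean of a gene's probe sets, every probe set on its own, preference for probe sets specific to 1 transcript, a filter on dim genes, quantile normalization again, median centring, eBayes with trend and robust settings, array weights, the replicate number as a block, other thresholds, and leaving out each array. A fit with the mean of the B cell list as a covariate was added after the data were seen. The fit was tested on simulated data with the control means of the 18194 genes and their spread as smoothed by eBayes, 200 of them changed, in 20 runs. It recovered 41.2% of genes changed by 0.5 on the log2 scale, 97.9% of those changed by 1, 99.7% at 1.5 and 99.8% at 3, and 6% of its calls were false. A list shifted by 0.4 was called in 20 of 20 runs and 0.7% of the other lists were called, but the simulated genes varied independently and those of the real lists did not. So many changed genes also ease the adjusted threshold, and the real fit called 5. The recovered shares may thus overstate what the real comparison could find, where a difference of -1.23 for Slc2a2 did not pass.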

Results

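The series asked which genes and pathways differ when Prox1, a homeobox transcription factor, is overexpressed in pancreatic beta cells of young mice. Whole pancreas at postnatal day 15 was profiled on 6 arrays, 3 from Prox1-OE mice, which carry a Prox1 transgene together with Ngn3-cre, and 3 from controls with Ngn3-cre alone. Ngn3-cre acts in the progenitors of the endocrine cells. Whole pancreas is mostly exocrine tissue, so each value averages islet cells with acinar, ductal, vascular and immune cells. Pearson correlations between arrays ran from 0.987 to 0.994. The first principal component held 34.6% of the variance and set Prox1-OE replicate 1 (score -28.7) apart from the other 5 arrays (-4.37 to 16.7), among which control replicate 3 was highest. The second component held 22.9% and set control replicate 3 (21.3) apart from the others (-11.7 to 6.42), and that array had the lowest weight (0.68) when arrays were weighted.

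Prox1 itself did not differ measurably. Its brightest probe set read 5.20 ± 0.19 (SD, n = 3) in Prox1-OE and 5.14 ± 0.41 in control, a log2 difference of 0.06 ± 0.20 (SE, limma adjusted p = 0.971), and lay at percentile 61.3 of all probe sets. The other probe sets of Prox1, at percentiles 35.1 and 4.3, differed by -0.03 and 0.02 (limma adjusted p = 0.990 and adjusted p = 0.987 over all probe sets). Probe sets of these arrays lie near the 3' end of transcripts and may fall outside the transgene's transcript, so they do not check the labels.

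Of 18194 genes, 4 rose and 1 fell in Prox1-OE pancreas, and all 5 did so with no overlap between the groups. Serpina6, which encodes the corticosteroid-binding globulin, rose 8.47-fold, from 4.02 ± 0.45 to 7.10 ± 0.36 on the log2 scale (log2 difference 3.08 ± 0.24 SE, adjusted p = 0.0179). Rbp4, the carrier protein of retinol in blood, rose by 1.43 ± 0.14 (adjusted p = 0.0247), from 7.05 ± 0.17 to 8.48 ± 0.22. Fam241b rose by 1.20 ± 0.10 (adjusted p = 0.0179) and Ap1s3, a subunit of a clathrin adaptor of the Golgi, by 0.998 ± 0.107 (adjusted p = 0.0444). Chga, which encodes chromogranin A of endocrine secretory granules, fell by 1.51 on the log2 scale (SE 0.14, adjusted p = 0.0217), from 8.96 ± 0.21 to 7.45 ± 0.19.

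At an unadjusted p under 0.05, 535 genes were higher and 674 lower, where 910 in all are expected by chance. The groups did not overlap for 12.1% of genes (10% by chance). The 5 genes kept their direction without any one array, but none of them passed the threshold without Prox1-OE replicate 1, Prox1-OE replicate 3 or control replicate 2. Without control replicate 1, 1 of them passed, and without Prox1-OE replicate 2 or control replicate 3, 3 passed. With the B cell list as a covariate, added after the data were seen, 0 genes passed and the 5 had adjusted p between 0.321 and 0.478. Their differences stayed near those without it (Serpina6 3.13 ± 0.33 SE, Rbp4 1.23 ± 0.15, Fam241b 1.13 ± 0.14, Ap1s3 1.0 ± 0.15, Chga -1.45 ± 0.18), with larger standard errors. Ap1s3 also missed the threshold with quantile normalization again (adjusted p = 0.0579) and with every probe set on its own (0.0651). When the replicate number was a block, 2 of the 5 passed, and Chga (limma adjusted p = 0.0519), Fam241b (0.0922) and Ap1s3 (0.136) did not.

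Genes of beta cell identity and function were lower in Prox1-OE pancreas: 17 of the 18 measured members had a negative difference. None passed over all genes, and 5 fell when adjusted over the list alone. Slc2a2, the glucose transporter of beta cells, fell by 1.23 ± 0.18 (SE; limma adjusted p = 0.00203, adjusted over the list alone), and Nkx6-1, a beta cell transcription factor, fell by 0.67 ± 0.11 (adjusted p = 0.00286). Slc30a8, the zinc transporter of insulin granules, fell by 1.05 ± 0.19 and Neurod1, an endocrine transcription factor, fell by 0.75 ± 0.14 (both with limma adjusted p = 0.00346). The fifth, G6pc2, a glucose-6-phosphatase of islets, differed by -1.40 ± 0.32 (limma adjusted p = 0.00774). Camera placed the list below other genes (adjusted p = 3.02e-08), with adjusted p = 0.255 with an estimated correlation. Without any one array, 5 to 7 members passed over the list alone.

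The abundant beta cell hormones did not pass the threshold. Ins2, one of the insulin genes, read 13.03 ± 0.41 in control and 12.84 ± 0.17 in Prox1-OE (log2 difference -0.18 ± 0.20, limma adjusted p = 0.878), from a probe set that can also bind near-identical transcripts. Iapp, the islet amyloid peptide released with insulin, differed by -0.15 ± 0.15 (limma adjusted p = 0.864). Among the other panel genes, Pdx1, a beta cell transcription factor, differed by -0.22 ± 0.15 and Ucn3, a peptide of mature beta cells, by -0.45 ± 0.17 (limma adjusted p = 0.0787 over the list alone). Neurog3, the endocrine progenitor factor, differed by -0.17 ± 0.10.

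**Figure D1:**
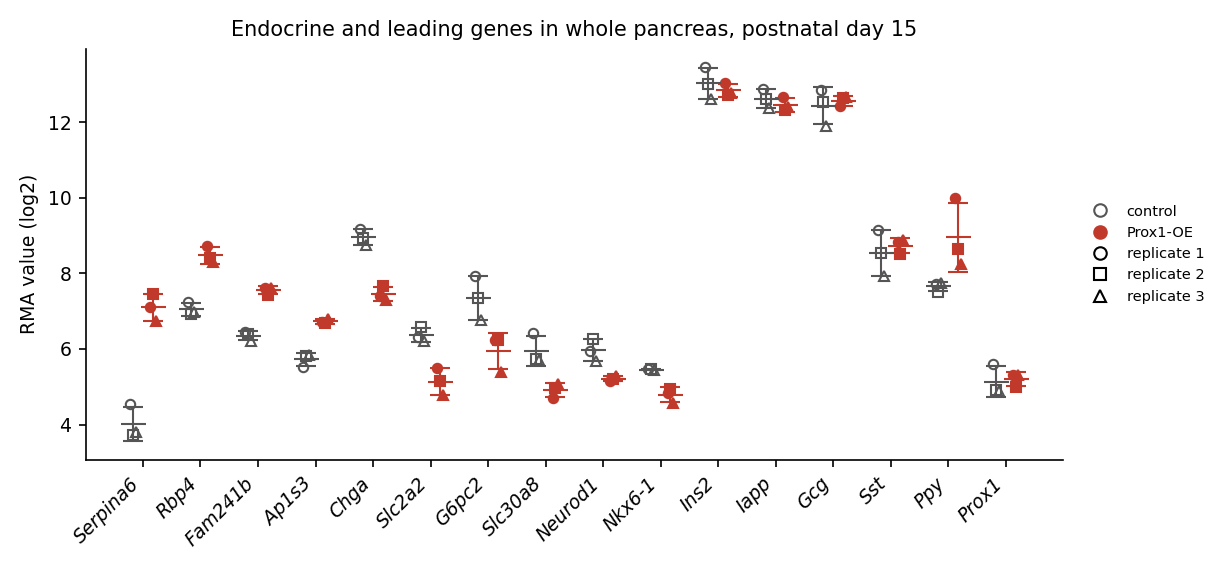
RMA values (log2, vertical axis) of leading and endocrine genes on each array, open symbols for control and filled symbols for Prox1-OE, with shapes for replicate numbers and bars for the mean and SD of 3 arrays. Serpina6 lies between 6.74 and 7.46 in Prox1-OE and between 3.71 and 4.53 in control, while the groups overlap for Ins2, Iapp, Gcg, Sst and Prox1.

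Secretory genes shared by all endocrine cells were also lower. Of 20 measured members 16 had a negative difference, and Chga was the 1 that passed, over all genes and over the list alone. Ptprn2, a granule membrane protein, differed by -0.54 ± 0.15 and Snap25, of the vesicle fusion machinery, by -0.38 ± 0.12, neither past the threshold. Camera gave adjusted p = 4.51e-04, with adjusted p = 0.498 with an estimated correlation. Without control replicate 1, the control with the highest level of the list, camera's adjusted p was 0.211. The list's mean over control was -0.24, -0.23 and -0.26 on the Prox1-OE arrays. On control replicates 1, 2 and 3 it was 0.22, -0.02 and -0.20, so control replicate 3 lay near the Prox1-OE arrays. Ins2 (13.44, 13.02 and 12.62), Gcg (12.9, 12.5 and 11.9) and Sst (9.15, 8.54 and 7.93) fell in the same order over the controls.

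Markers of delta, PP and epsilon cells were higher as a list, led by 2 members. Rbp4, also a delta cell marker, passed over all genes. Ppy, which encodes pancreatic polypeptide, rose by 1.29 ± 0.38 when adjusted over the list alone (limma adjusted p = 0.0322, and 0.690 over all genes). It read 9.99 on Prox1-OE replicate 1, 8.64 and 8.24 on the other Prox1-OE arrays, and 7.52 to 7.75 in control, and the difference was 0.78 without Prox1-OE replicate 1 and 0.51 with the B cell covariate. Over the list alone, 1 member passed in place of 2 without any one control and with that covariate. Sst, the somatostatin gene, differed by 0.19 ± 0.27, Pyy, of peptide YY, by 0.22 ± 0.17, and Ghrl, of ghrelin, by -0.21 ± 0.09 (limma adjusted p = 0.112 over the list alone). Camera gave the 7 genes adjusted p = 0.0174, with adjusted p = 0.498 with an estimated correlation. The call ended without control replicate 2 (0.0598), without control replicate 3 (0.0769) and with the B cell covariate (0.380).

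Of 9 alpha cell genes 7 had a negative difference and none passed (camera adjusted p = 0.135). Gcg, the glucagon gene, differed by 0.13 ± 0.22, Pou3f4, an alpha cell transcription factor, by -0.41 ± 0.13, and Sstr2, a somatostatin receptor, by -0.29 ± 0.09. The list of genes of immature beta cells or kept low in mature ones gave adjusted p = 0.0973, and its leading member Cxcl12, a chemokine, differed by 0.84 ± 0.28.

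Macrophage genes were higher in Prox1-OE pancreas, with 17 of 19 members positive. None passed over all genes, and 11 rose when adjusted over the list alone. C1qc, a chain of complement C1q, rose by 0.59 ± 0.13, Fcgr3, an antibody receptor, by 0.56 ± 0.13, Cd68, a lysosomal marker of macrophages, by 0.62 ± 0.15, and Ctss, the protease cathepsin S, 2.83-fold (all with limma adjusted p = 0.0143 over the list alone). The mean of the list over control was 0.99 on Prox1-OE replicate 1 and 0.39 and 0.37 on the others, against -0.14 to 0.14 on the controls. Camera gave adjusted p = 3.99e-14, with adjusted p = 0.498 with an estimated correlation. Without control replicate 2, or with the B cell covariate, 0 members passed over the list alone, and without control replicate 3, 5 passed.

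Interferon response genes were higher as a list in the same arrays, with 19 of 21 members positive, 0 past the threshold over all genes and 4 when adjusted over the list alone. Gbp2 (0.59 ± 0.12) and Gbp3 (0.47 ± 0.12), guanylate-binding proteins, rose, as did Ifi27l2a (0.78 ± 0.20) and Ifit1 (0.43 ± 0.12), which interferon induces. Their limma adjusted p over the list alone ran from 0.0206 to 0.0386. Ifit1 (3.10 in control and 3.52 in Prox1-OE) and Gbp3 (3.76 and 4.22) read below the array medians, near background. The list's mean over control was 0.34, 0.16 and 0.27 on the Prox1-OE arrays and between -0.01 and 0 on the controls. Camera gave adjusted p = 1.96e-07, with adjusted p = 0.180 with an estimated correlation. The list-alone count was 0 without Prox1-OE replicate 3 or control replicate 1, 1 without control replicate 2, without control replicate 3 or with the B cell covariate, and 2 without Prox1-OE replicate 1.

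B cell and plasma cell genes were higher mainly on Prox1-OE replicate 1. The list's mean over control was 1.42 there, 0.43 on replicate 3 and 0.11 on replicate 2. Ms4a1, which encodes the B cell antigen CD20, differed by 2.26 ± 0.62 and Ighm, the heavy chain of immunoglobulin M, by 1.44 ± 0.48, and 0 of 15 members passed over all genes or over the list alone. Camera gave adjusted p = 1.87e-05, with adjusted p = 0.498 with an estimated correlation. Without Prox1-OE replicate 2, 8 members passed over the list alone.

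The same array was also the highest for T and NK cell (0.50), lymphatic endothelial (0.61), fibroblast and matrix (0.49) and Reg family and injury genes (0.96). None of these lists had a member past either threshold. Camera's adjusted p was 0.0459 for T and NK cell, 0.00215 for lymphatic endothelial, 1.12e-04 for fibroblast and 0.00366 for Reg family genes. They had adjusted p = 0.638, adjusted p = 0.498, adjusted p = 0.537 and adjusted p = 0.498 with an estimated correlation. Without Prox1-OE replicate 1 the camera values were 0.496, 0.146, 0.253 and 0.146, and of the 6 fits that each left out 1 array, only that without Prox1-OE replicate 2 kept the T and NK call. Nkg7, of cytotoxic lymphocytes, differed by 0.42 ± 0.11, Lyve1, a lymphatic marker, by 0.68 ± 0.28, Fn1, fibronectin, by 0.42 ± 0.17 and Vim, vimentin, by 0.32 ± 0.11.

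**Figure D2:**
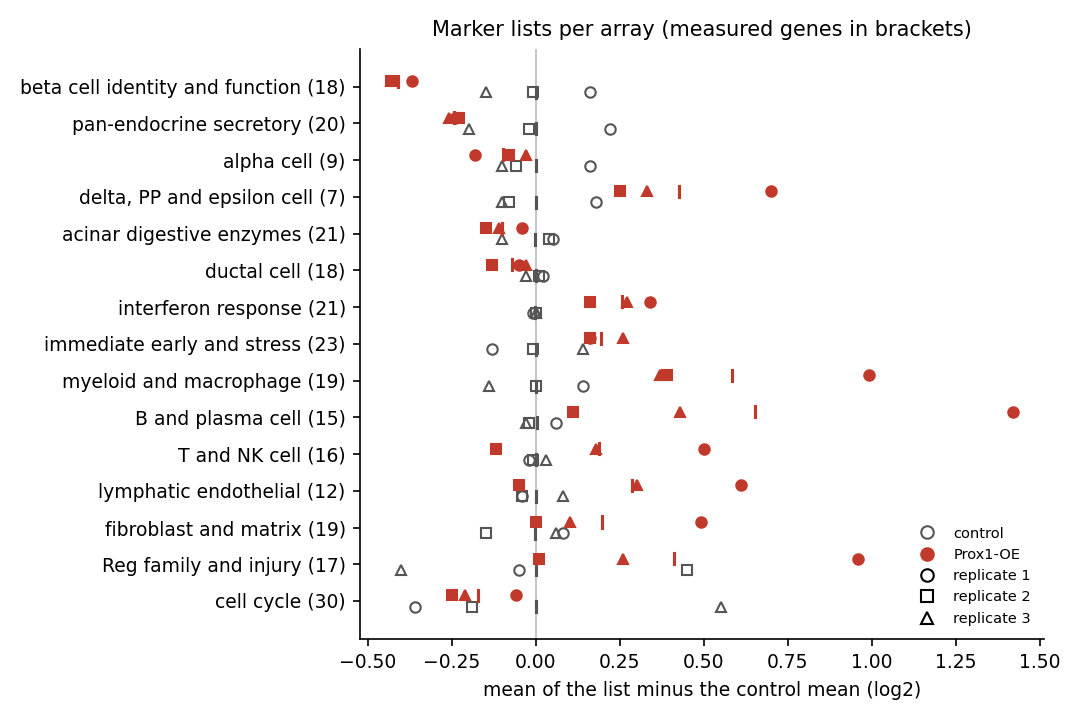
Mean log2 value of each marker list minus its control mean (horizontal axis) on each array, open symbols for control and filled symbols for Prox1-OE, with the number of measured genes in brackets and short bars for group means. The beta cell list lies between -0.43 and -0.37 on the Prox1-OE arrays and between -0.15 and 0.16 on the controls, and the B cell list reaches 1.42 on Prox1-OE replicate 1.

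Immediate early and stress genes were higher as a list (21 of 23 members positive, none past either threshold). Camera gave adjusted p = 8.79e-05, with adjusted p = 0.498 with an estimated correlation. Jun, a transcription factor of the early response, differed by 0.26 ± 0.08, and the chaperone genes Hspa1b and Hsph1 by 0.70 ± 0.25 and 0.76 ± 0.30 (0.43 to 0.99 and 0.48 to 1.08 without any one array).

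Exocrine genes did not pass in the fit described. Of 21 digestive enzyme genes 19 had a negative difference (median -0.05, camera adjusted p = 0.0973). Many of them, such as Cela3b (14.79 in Prox1-OE and 14.89 in control), read near the highest value of the arrays (14.92). Probe sets this bright may be saturated and may hide a change. Acinar transcription and secretion genes gave the same camera adjusted p, with Nr5a2, an acinar transcription factor, at -0.28 ± 0.10 and the water channel gene Aqp12 at -0.30 ± 0.11. Digestive enzyme genes were called lower with every probe set on its own (0.0443) and with the filter on dim genes (0.0451), and acinar transcription and secretion genes with those settings (0.00756 and 0.0394) and without Prox1-OE replicate 3 (0.0133). Ductal genes gave adjusted p = 0.204. Cell cycle genes gave 0.0660, with 25 of 30 members negative. Their mean over control was 0.55 on control replicate 3 and -0.36 and -0.19 on the other controls, and Aurkb and Nusap1, genes of cell division, differed by -0.36 ± 0.24 and -0.45 ± 0.31. Without control replicate 3 the list turned and was higher in Prox1-OE (adjusted p = 0.00796), and it was called lower without control replicate 1 (3.69e-05), control replicate 2 (0.00717) or Prox1-OE replicate 1 (0.0235).

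Camera's adjusted p was 0.0536 for erythroid, 0.125 for skeletal muscle, 0.166 for smooth muscle and pericyte, 0.25 for Schwann and neural, 0.258 for neutrophil, 0.286 for blood endothelial, 0.543 for hepatocyte and intestinal and 0.561 for adipocyte genes. Over their lists alone, Mylpf, a muscle myosin light chain, fell by 0.52 ± 0.13 (limma adjusted p = 0.0467) and Vil1, the microvillus protein villin, fell by 0.43 ± 0.10 (adjusted p = 0.0273), both with mean levels under 5. Pathway lists gave 0.0973 for amino acid metabolism, 0.147 for the unfolded protein response, 0.147 for glycolysis, 0.482 for oxidative phosphorylation, 0.610 for lipid and sterol synthesis and 0.834 for the circadian clock, where the median (0.00) and the mean (-0.02) lay on either side of 0.

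In all, 9 of the 31 lists were higher and 2 lower by camera with the preset correlation, and 0 passed with an estimated correlation or by fry. Other splits of the 6 arrays into 3 and 3, which mix the genotypes, called 5 to 13 lists in the same way. Without Prox1-OE replicate 1, 5 lists were higher, and 5, 4 and 6 were lower without Prox1-OE replicate 2, Prox1-OE replicate 3 and control replicate 3. The difference between 3' and 5' control probe sets, a measure of RNA degradation, was 0.93 ± 0.01 in Prox1-OE and 0.95 ± 0.04 in control (exact two-sided permutation p = 0.7, where 0.1 is the smallest possible).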

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

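All tests of explanations in this part were chosen after the results were seen. Outside the named genes, 1 probe set without a single gene symbol passed the threshold. It differed by -0.88 (log2), from 7.52 ± 0.06 in control to 6.64 ± 0.03 in Prox1-OE (adjusted p = 0.0342 over all probe sets), and was not used in the comparisons of genes.

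The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5 genes and the highest other split 2, so that 1 split gave as many. The real split gave 11 lists by camera and the highest other 13, so that 6 of the 10 splits gave as many or more. The 9 other splits called 5 to 13 lists, so a count of lists of this size also arises between groups that mix the genotypes. The beta cell list had its smallest unadjusted camera p in the real split (1.95e-09, against 5.46e-05 in the next), and so did the macrophage list (1.29e-15, against 1.37e-09). With 10 splits this cannot be told from chance, and splits that mix the genotypes also gave both lists small values.

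Lower Slc2a2, Nkx6-1, Slc30a8, Neurod1 and G6pc2, the members that passed over their list alone, could come from fewer beta cells or from dilution by other tissue. Dilution in Prox1-OE replicate 1 is argued against by a mean of -0.43 for all 18 members without that array (95% interval -0.79 to -0.07), against -0.41 with it. Fewer beta cells as the whole cause would lower Ins2 and Iapp as much as other members made by beta cells alone and read well above background. The 16 others, none picked by its change, differed from Ins2 and Iapp by -0.27 within arrays (95% interval -0.68 to 0.15), with 0 of the 16 past an adjusted p of 0.05. Some of the 16 read below the array medians (Npy1r 3.28, Trpm5 3.97, Ucn3 3.98 and Glp1r 4.25 in control), where RMA compresses differences. This can pull the difference toward 0. Members not made by beta cells alone can do the same, and Neurod1, an endocrine factor, is among them. Ins2 and Iapp were able to vary: control replicates 1 and 3 differed by 0.66 in their mean, and by 0.45 in that of the 5 picked genes. A first test on the 5 picked genes alone gave -0.85, but picking them by their change can make that value too large. A loss of beta cells cannot be told apart from an effect of Prox1 on these genes within beta cells, since the interval includes 0 and whole pancreas mixes both.

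Higher B cell and macrophage genes might reflect lymph node tissue dissected with the pancreas. Such tissue in Prox1-OE replicate 1 alone is argued against by replicate 3, whose B cell list lay 0.38 above the highest control (control SD 0.05), and by the macrophage list, which differed by 0.38 without replicate 1 (95% interval 0.04 to 0.72), while the B cell list then differed by 0.27 (-0.13 to 0.67). For lymph node in every Prox1-OE pancreas, the first test, on 11 genes of lymph node vessels and follicles, gave replicate 2 a level 0.28 above the highest control, which goes with it. That list holds genes of all leukocytes, so other lists were added after this value was seen: replicate 2 lay at -0.15 from the highest control for T and NK cell genes and 0.05 above it for B cell genes (control SD 0.05), and Glycam1, of lymph node vessels, read 3.26 there, below every control. On replicates 1 and 3 the list of the first test lay 1.87 and 0.98 over the control mean, against -0.03 to 0.02 on the controls. Glycam1 read 8.49 and 6.83 there. These values go with lymph node in replicates 1 and 3, for which no test was set. Lymph node in every Prox1-OE pancreas stays open, as does an immune response to the transgene, which was not tested.

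Higher Serpina6 and Rbp4, both abundant in liver, and lower Chga could have technical sources. Liver tissue as the source of the Serpina6 difference is argued against by a mean difference of 0.25 (95% interval -0.19 to 0.69) for Alb, Apoa1, Apoa2, Ahsg and Fgb, among which Alb differed by -0.26 and Ahsg by 1.20, against 2.16 to 4.0 for Serpina6. No such comparison was made for Rbp4. Ahsg (3.99) and Apoa1 (4.07) read below the array medians in control, where RMA compresses differences. Chga and Serpina6 both lie on chromosome 12 with 16 measured genes between them, which raised an inserted or different chromosome segment as a candidate source. The 36 genes around them had a median absolute t at percentile 66.1 of 10000 random windows; a first rule, set at percentile 75 of that median alone, would have counted this against the explanation, and the count of genes was added after that value was seen. With 6 genes at an unadjusted p under 0.05 (percentile 95.8, random median 2), the segment cannot be told apart from an effect of Prox1. Among the 6 was Ifi27l2a (0.78), also counted among the interferon genes that rose, so those observations are not independent.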

How the results depend on the processing

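The fit with the B cell covariate was chosen after seeing the data, the other settings before. The 5 genes kept their direction in every setting run, but not every call (Ap1s3 had adjusted p = 0.0579 with quantile normalization again and 0.0651 with every probe set on its own). Leaving out 1 array gave 0 to 2 genes higher and 0 to 2 lower, 5 to 11 lists higher and 3 to 6 lower, Prox1 at -0.06 to 0.30 and RNA quality at -0.031 to 0.005. Its lowest and highest values crossed 0 for Ins2 (-0.39 to 0.03), Gcg (-0.13 to 0.34) and Sst (-0.11 to 0.50). Without 1 array, the uncalled genes named in the text that moved by over 1.5 times also included Iapp (-0.28 to -0.03), Pdx1 (-0.36 to -0.10), Ucn3 (-0.56 to -0.24), Neurog3 (-0.25 to -0.09), Pyy (0.03 to 0.33), Ighm (0.82 to 1.84), Lyve1 (0.33 to 0.99), Fn1 (0.25 to 0.54), Aurkb (-0.52 to -0.09), Nusap1 (-0.67 to -0.15), Postn (0.18 to 0.73), Hspa1b and Hsph1. Lists whose direction turned without at least 1 array had adjusted p of 0.0201 to 0.8 (smooth muscle), 0.0131 to 0.763 (blood endothelial), 0.0201 to 0.951 (adipocyte), 0.133 to 0.872 (hepatocyte and intestine), 0.0259 to 0.873 (lipid and sterol), 0.272 to 0.925 (circadian), and 3.69e-05 to 0.185 (cell cycle). The calls of the pan-endocrine (2.12e-08 to 0.211) and the delta, PP and epsilon list (0.00204 to 0.0769) ended without at least 1 array. Fewer arrays lower the power, and other causes were not tested.

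The number of lower lists was 4 with the mean of probe sets, quantile normalization again, median centring or the replicate block, 6 with the filter on dim genes and 8 with every probe set on its own, where 2 probe sets were lower, that of Chga and 1 without a single gene symbol. Lipid and sterol genes turned with specific probe sets (adjusted p = 1) and T and NK cell (0.422) and circadian genes (0.744) with the filter. The T and NK call also ended with median centring (0.0523) and array weights (0.0634). Lists called lower that were not in the fit described included erythroid genes (every probe set 0.0405, median centring 0.0433, array weights 0.0419, replicate block 0.0416, without Prox1-OE replicate 2 4.1e-04, without control replicate 3 0.0103) and amino acid genes (mean of probe sets 0.0173, every probe set 0.0241, filter 0.0457, quantile 0.0326, without Prox1-OE replicate 2 0.0171, without control replicate 3 0.00529). Cell cycle genes were also called lower with the mean of probe sets (0.0173), every probe set (0.00381), the filter (0.0492), quantile (0.0414), median centring (0.0317) and the block (0.0292). Unfolded protein response genes were called lower without Prox1-OE replicate 2 (0.0457) and control replicate 3 (4.91e-04), alpha cell genes with every probe set (0.04) and without control replicate 3 (0.0366), and skeletal muscle genes without control replicate 1 (0.0415). Immature beta cell genes were called higher with the block (0.0487) and without Prox1-OE replicate 2 (0.0206). RNA quality was 0.041 from Gapdh alone. The cause was not tested.

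With an estimated correlation or fry, 0 lists were higher and 0 lower. Adjusted p was 0.255 and 0.183 for beta cell, 0.498 and 0.469 for pan-endocrine, for delta, PP and epsilon and for B cell, 0.498 and 0.430 for macrophage and 0.180 and 0.147 for interferon genes. The interferon list lost its call although its estimated correlation (0.016) was close to the preset 0.01. Both forms of camera also differ in degrees of freedom (4 with an estimated correlation), so a lost call need not come from correlation between genes.

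With the replicate number as a block, 2 genes were higher and 0 lower, and Chga (adjusted p = 0.0519), Fam241b (0.0922) and Ap1s3 (0.136) missed the threshold with differences as large as before. The block left 2 residual degrees of freedom, and the standard error of Chga was 0.117 with it and 0.137 without it. Correlations of deviations were weak, at 0.044, 0.142 and 0.109 for like numbers 1, 2 and 3, and -0.142 to 0.012 for unlike numbers. They neither show nor exclude that the numbers pair the samples. Every sample correlated best with its own number. Deviations from a group's own mean tie these correlations to each other, and how often arbitrary numbers would give this was not computed.

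With the B cell covariate, 0 genes were higher and 0 lower, with differences near those without it (Serpina6 3.13, Chga -1.45), 3 lists higher and 4 lower, and Prox1 (-0.09), Pyy (-0.10) and Postn (-0.01) turned. The delta, PP and epsilon list had adjusted p = 0.380, and 12 lists turned direction. For the B cell list (0.703) a mean difference of 0 is fixed by construction, since its mean is the covariate, so its turn carries no information. The others were fibroblast (0.675), smooth muscle (0.00225), blood endothelial (0.310), lymphatic (0.805), T and NK cell (0.189), neutrophil (0.805), adipocyte (0.805), hepatocyte and intestine (0.839), lipid and sterol (0.380), amino acid (0.923) and circadian (0.703). The covariate overlaps with genotype, and the cause of the other turns was not tested. Dim genes lie near background, where RMA understates differences.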

Other observations

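All genes, lists and tests in this part were chosen after the values were seen. Chaperones of the heat shock response were among the larger differences that did not pass the threshold. Hspb1, a small heat shock protein, differed by 1.63 ± 0.30 (adjusted p = 0.562), Hsp90aa1, an inducible cytosolic chaperone, by 0.91 ± 0.15 (adjusted p = 0.451) and Hspa4l, a relative of Hsp110, by 1.14 ± 0.25 (adjusted p = 0.690), each without overlap between the groups on the probe set used. Other probe sets of Hspa4l differed by only 0.18 to 0.52, some with overlap, and those of Hsp90aa1 by -0.02 to 1.09. Hspa8, the constitutive relative of Hsp70, differed by -0.13 ± 0.13. The mean of 18 chaperone genes over control was 0.54, 0.59 and 0.16 on the Prox1-OE arrays and -0.06, 0.22 and -0.16 on the controls, so the groups overlapped.

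Glycam1, a mucin of lymph node vessels, read 8.49 on Prox1-OE replicate 1, 6.83 on replicate 3 and 3.26 on replicate 2, against 3.30 to 3.72 in control. Ptprc, the leukocyte antigen CD45, read 8.92, 7.56 and 5.55 on the same arrays and 5.19 to 5.38 in control, and Marco, a macrophage scavenger receptor, read 7.02, 6.14 and 4.76 against 3.83 to 4.64.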
